A study of Arabidopsis thaliana with 12 samples.

How the data were processed

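The values analysed are one intensity per row and array, normalized by RMA, as deposited by the authors; scans and probe-level values were not reprocessed. Per the labels' protocols, rosettes of soil-grown plants were placed on wet paper in dishes and kept in darkness. The fifth leaf of several rosettes was taken at each harvest, and RNA was extracted with Trizol and a column kit. Per the same protocols, cDNA was labelled with Cy3 and hybridized to NimbleGen arrays, one sample per array. Per the submitters' processing notes, the intensities were normalized with RMA; its version, the slides, the scans and any batches are not given in the sources used here. Median intensities of the 12 arrays lay between 577 and 634 and the brightest values between 41635 and 43795, so the arrays were on one scale. Without detection calls, fold changes of dim genes are uncertain, and those of genes near the maximum may be compressed, a matter that leaving out the dimmest 30% of genes tested in part (1145 genes then shared a direction at both days).

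The table held 31524 rows and was turned to log2. Where several rows belonged to one locus (3675 genes), the row with the highest mean was kept, which left 27143 genes. A reference table of RefSeq genes gave symbols and chromosome order only; it matched 26555 genes, of which 10379 had a symbol other than the locus. No filter on level was used, and 0 pairs of arrays were identical.

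Limma 3.58.1 in R 4.3.3 was used to fit a mean for each of the 4 groups over all 12 arrays, with 8 residual and 1.88 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold at an adjusted p of 0.05. The 6 comparisons were arf2-6 against Col-0 at day 3, at day 5 and averaged over both days, day 5 against day 3 in Col-0 and in arf2-6, and their interaction. Comparisons across both genotype and day were left out. The comparisons, the tests, the lists, the rule for naming genes and the alternatives, except where said, were chosen before the data were examined.

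Of 26 gene lists, 24 were fixed from background knowledge with 460 entries, and the others were the loci of the plastid and mitochondrial genomes. They covered senescence-associated genes, senescence transcription factors, senescence repressors, chlorophyll breakdown, photosystem and light harvesting, the Calvin cycle, autophagy, and dark starvation with amino acid breakdown. For hormones and defence they covered auxin response, other auxin response factors, genes linked to ARF2, ethylene, abscisic acid, jasmonate, salicylic acid and cytokinin. The rest covered cell expansion and division, flavonoid and anthocyanin, glucosinolate, circadian clock, reference genes, markers of epidermis and guard cells, of phloem and xylem, and of meristem and flower, and plastid-encoded and mitochondrion-encoded genes. A list needed 5 measured members. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated from the residuals and with fry. Member counts were also adjusted over the list alone. The list tests share the spread of 12 arrays and their genes move together, so the value with an estimated correlation is given beside each call made with all arrays at the preset, and not beside those gained only in an alternative.

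The rule for naming genes took ARF2 first. In each comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups of arrays did not overlap and that had a symbol, plus the largest pair of rises and of falls of any gene. In the interaction the threshold alone applied. Where no gene passed, it took the 5 genes with the smallest unadjusted p, as values with no permutation test. From each list it took up to 4 members with the smallest p. Lower ranks may be left out, and genes outside the rule are said to be so.

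Covariances and correlations across genes were set beside the covariance that shared arrays alone give and beside 1000 simulated sets of unchanged groups. Alternatives were a further quantile normalization, centring on the median, leaving out the dimmest 30% of genes, a trended and robust variance model, array weights, replicate number as a block, rows of a gene averaged, a 2-fold minimum, a fit to the 6 arrays compared, and each array left out in turn. A fit without Col-0 day 3 replicate 1 and Col-0 day 5 replicate 3 and a scaling to the 8 reference genes were chosen after seeing the data.

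A self-test drew values with the mean and spread of each gene, added log2 differences of 1 or of 3, up or down, to 100 genes each in arf2-6 at day 3, and ran the same steps. It recovered 25% of the genes at 1 and 84% at 3, with 4 false calls among 113. In a further draw, a list shifted by −0.5 in all arf2-6 arrays was recovered for the average over both days, and 0 other lists were called. Genes were drawn independently of each other. The self-test therefore does not check camera at its preset correlation for lists whose genes move together.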

Results

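Transcript levels were measured on 12 one-colour NimbleGen arrays of Arabidopsis leaves kept in darkness, a treatment that sets off leaf senescence. Leaves of the wild type Col-0 were set beside leaves of arf2-6, a mutant of the auxin response factor gene ARF2, at 3 and at 5 days of darkness, with 3 arrays in each of the 4 groups. The number of arrays limits the precision. The labels number the replicates without saying that they came from separate plants, so p-values measure the spread between these samples. Differences are on the log2 scale, arf2-6 minus Col-0 or day 5 minus day 3, and are printed ± their standard error. "Rose" and "fell" are used of genes past an adjusted p of 0.05 in limma.

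ARF2 itself (AT5G62000), a transcriptional repressor of the auxin response factor family, had a mean intensity of 11940 ± 1041 (SD, n = 3) in Col-0 at day 3 and 9914 ± 913 (SD, n = 3) at day 5. In arf2-6 it was 60.8 ± 10.1 (SD, n = 3) at day 3 and 60.6 ± 24.7 (SD, n = 3) at day 5. The 6 Col-0 arrays lay between 8860 and 12934 and the 6 arf2-6 arrays between 35.3 and 84.6. The lower quartile of all intensities on an array lay between 29.9 and 32.5. ARF2 fell by 7.53 ± 0.20 on average over both days (limma adjusted p = 1.16e-07) on the row kept, and the means differed by −8.67 on the other row of ARF2, where the arf2-6 arrays lay between 19.8 and 34.8. Levels in arf2-6 are so near the dim end that the size of the fall is uncertain, but the level went with the genotype label on all 12 arrays.

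The first principal component held 62.4% of the variance and set arf2-6 apart from Col-0. The arf2-6 arrays lay close together, from 49.98 to 102.1. The Col-0 arrays were spread out. At day 3, Col-0 replicates 2 and 3 lay at 12.4 and 4.55 and replicate 1 at −100.2, among the Col-0 day 5 arrays at −68.0, −126.9 and −199.8. The median SD of a gene within a group was 0.28 in Col-0 at day 3 and 0.35 at day 5, against 0.20 in each arf2-6 group, in log2 units.

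**Figure D1:**
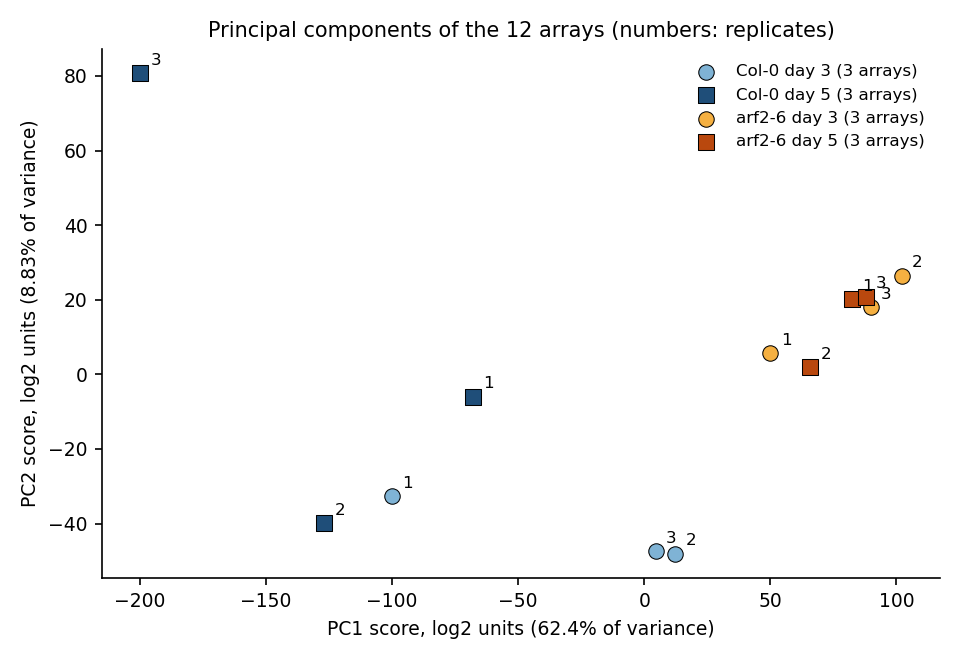
Scores of the 12 arrays on the first and second principal components of the log2 intensities, in log2 units, with 3 arrays per group and replicate numbers beside the points. The arf2-6 arrays lie between 49.98 and 102.1 on the first component, and Col-0 day 3 replicate 1 lies at −100.2, among the Col-0 day 5 arrays.

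The average of both days asks how leaves with little ARF2 transcript differ from the wild type in darkness, whatever the day. By camera, lists of senescence-associated genes, autophagy and dark starvation were lower in arf2-6 and lists of photosynthesis were higher, each with adjusted p = 0.624 with an estimated correlation. BFN1, a nuclease of senescing tissue, fell by 5.71 ± 0.50, and RNS1, a ribonuclease, by 5.33 ± 0.74. PCK2, a phosphoenolpyruvate carboxykinase, fell by 7.77 ± 0.75. LHCB1.5, a light-harvesting protein of photosystem II, rose by 1.4 ± 0.18, and FBA2, a plastid aldolase of the Calvin cycle, by 2.57 ± 0.56.

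Of 30 senescence-associated genes, 15 fell, 0 rose and 15 did neither (16 fell when adjusted over the list alone), with a median of −0.43. They included DIN9, a dark-induced mannose-6-phosphate isomerase, at −2.47 ± 0.18, and GLN1.4, a cytosolic glutamine synthetase, at −1.79 ± 0.18. Camera, which sets a list against all other genes, gave the list an adjusted p of 6.77e-05, and adjusted p = 0.624 with an estimated correlation. Of 25 autophagy genes, 16 fell, 0 rose and 9 did neither (16 fell when adjusted over the list alone), among them ATG8H, a protein of the autophagosome membrane, at −2.47 ± 0.25, and ATG7, which activates ATG8, at −2.19 ± 0.25. The autophagy median was −0.49, with a camera adjusted p of 8.10e-07, and adjusted p = 0.624 with an estimated correlation. Of 27 genes of dark starvation and amino acid breakdown, 12 fell, 1 rose and 14 did neither, with the same counts when adjusted over the list alone. PRODH2 and P5CDH, enzymes of proline breakdown, fell by 2.15 ± 0.24 and 0.79 ± 0.12, and the member that rose was GDH1, a glutamate dehydrogenase, at 0.75 ± 0.12. Their median was −0.26, with a camera adjusted p of 0.00263, and adjusted p = 0.624 with an estimated correlation.

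Among 30 transcription factors of senescence, 9 rose, 13 fell and 8 did neither, with the same counts when adjusted over the list alone. NAC055 fell by 1.54 ± 0.16 while WRKY53 rose by 2.22 ± 0.28. This list did not pass camera (median −0.03, adjusted p = 0.446). Of 10 repressors of senescence, 4 rose, 0 fell and 6 did neither (4 rose when adjusted over the list alone), including CGA1, a GATA factor of chloroplast development, at 2.23 ± 0.25 (list median 0.31, camera adjusted p = 0.446). Of 14 genes of chlorophyll breakdown, 7 fell, 2 rose and 5 did neither, with the same counts when adjusted over the list alone (list median −0.24, camera adjusted p = 0.143). NYE1, which removes magnesium from chlorophyll a, fell by 0.81 ± 0.11, and HCAR, which reduces a chlorophyll intermediate, rose by 1.06 ± 0.19.

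Of 47 genes of the photosystems and light harvesting, 31 rose, 1 fell and 15 did neither (36 rose and 1 fell when adjusted over the list alone), with a median of 0.87. PETE1, a plastocyanin, rose by 2.02 ± 0.34 and LHCB3 by 1.75 ± 0.30, and the member that fell was LHCA5, chosen for naming after its value was seen, at −0.99. Camera gave the list an adjusted p of 1.56e-08, and adjusted p = 0.624 with an estimated correlation. Of 20 Calvin cycle genes, 8 rose, 0 fell and 12 did neither (8 rose when adjusted over the list alone), and HCEF1, a plastid fructose-1,6-bisphosphatase, rose by 2.53 ± 0.59. The Calvin cycle median was 0.58 (0.29 without Col-0 day 5 replicate 3), with a camera adjusted p of 0.000608, and adjusted p = 0.624 with an estimated correlation. Of 67 plastid-encoded genes, 30 rose, 0 fell and 37 did neither (38 rose when adjusted over the list alone), with a median of 0.36 and a camera adjusted p of 1.74e-08, and adjusted p = 0.624 with an estimated correlation. Of 94 mitochondrion-encoded genes, 50 rose, 0 fell and 44 did neither (51 rose when adjusted over the list alone), with ATMG01290 at 2.16 ± 0.20. The mitochondrial median was 0.40, with a camera adjusted p of 1.56e-08, and adjusted p = 0.624 with an estimated correlation.

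Among hormone lists, jasmonate and cytokinin genes passed camera. Of 18 jasmonate genes, 12 fell, 1 rose and 5 did neither (13 fell and 1 rose when adjusted over the list alone). They included JAZ10 and JAZ5, repressors that jasmonate induces, at −2.83 ± 0.32 and −3.58 ± 0.48, and LOX3, a lipoxygenase of jasmonate synthesis, at −3.46 ± 0.47. The jasmonate gene that rose was LOX2, another such lipoxygenase, chosen for naming after its value was seen, at 0.74. The jasmonate median was −0.57, with a camera adjusted p of 0.000167, and adjusted p = 0.624 with an estimated correlation. Of 16 cytokinin genes, 4 fell, 0 rose and 12 did neither (4 fell when adjusted over the list alone), with a median of −0.58. The cytokinin genes with the smallest p included CKX5, CKX3 and CKX2, oxidases that break cytokinin down, at −2.04 ± 0.28, −3.62 ± 0.72 and −5.34 ± 1.12. The cytokinin list had a camera adjusted p of 0.0162, and adjusted p = 0.624 with an estimated correlation; with array weights the camera value was 0.0699, and without Col-0 day 5 replicate 3 the median was −0.26.

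The other hormone lists did not pass camera. Of 22 ethylene genes, 5 rose, 9 fell and 8 did neither, with the same counts when adjusted over the list alone (median −0.23, camera adjusted p = 0.143), and ACS2 and ACS6, which make the ethylene precursor, fell by 3.41 ± 0.34 and 3.90 ± 0.56. Of 35 auxin response genes, 14 rose, 3 fell and 18 did neither, with the same counts when adjusted over the list alone (median 0.38, camera adjusted p = 0.154). GH3.2, an enzyme that couples auxin to amino acids, fell by 5.4 ± 0.92, and IAA27 and IAA29, repressors of auxin signalling, rose by 1.44 ± 0.27 and 3.05 ± 0.63. Without arf2-6 day 3 replicate 1 the auxin list passed camera at 0.0177. Of 14 other auxin response factors, 5 rose, 1 fell and 8 did neither (6 rose and 1 fell when adjusted over the list alone), with ARF1 at 1.22 ± 0.19 and ARF5 at −2.37 ± 0.46 (median 0.18, camera adjusted p = 0.335). Of 11 genes linked to ARF2, 2 rose, 2 fell and 7 did neither (3 rose and 2 fell when adjusted over the list alone). HB33, a zinc finger homeobox gene, rose by 3.97 ± 0.33 (list median 0.44, camera adjusted p = 0.507). Of 21 abscisic acid genes, 7 rose, 2 fell and 12 did neither, with the same counts when adjusted over the list alone (median 0.03, camera adjusted p = 0.413). RD29A and RD22, which answer to abscisic acid and drought, rose by 4.26 ± 0.68 and 4.33 ± 0.88. Of 15 genes of salicylic acid and defence, 2 rose, 6 fell and 7 did neither (3 rose and 7 fell when adjusted over the list alone), with a median of −1.75 and a camera adjusted p of 0.143. PR5 and PR2, defence proteins, rose by 3.28 ± 0.29 and 3.75 ± 0.58, while PBS3, an enzyme of salicylic acid synthesis, fell by 4.62 ± 1.09. The salicylic acid list passed camera without Col-0 day 3 replicate 2 (0.0124) or Col-0 day 5 replicate 2 (0.0140).

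Further lists stayed above a camera adjusted p of 0.05. Of 18 genes of cell expansion and division, 1 rose, 2 fell and 15 did neither (1 rose and 1 fell when adjusted over the list alone; median 0.38, adjusted p = 0.778), with XTH15 and XTH17, enzymes of wall loosening, at 3.49 ± 0.76 and −2.69 ± 0.49. Of 15 flavonoid and anthocyanin genes, 0 passed limma over all genes or adjusted over the list alone (median 0.15, camera adjusted p = 0.725). Of 18 glucosinolate genes, 2 rose, 3 fell and 13 did neither (1 rose and 1 fell when adjusted over the list alone; median 0.30, adjusted p = 0.839), with SOT16, a sulfotransferase, at −1.07 ± 0.21. Of 12 clock genes, 3 rose, 2 fell and 7 did neither (4 rose and 4 fell when adjusted over the list alone), with ELF3 at 0.50 ± 0.08 and LHY at −0.89 ± 0.18. The clock median was −0.04, while its mean of 0.06 and the test pointed upward (adjusted p = 0.839). Of 8 reference genes, 1 rose, 0 fell and 7 did neither over all genes and when adjusted over the list alone (median 0.10, adjusted p = 0.335). It was PP2AA3, a subunit of a protein phosphatase, at 0.28 ± 0.08. Of 12 markers of epidermis and guard cells, 4 rose, 2 fell and 6 did neither over all genes and when adjusted over the list alone (median 0.18, adjusted p = 0.566), with PDF2 at 1.66 ± 0.28. Of 11 markers of phloem and xylem, 3 rose, 0 fell and 8 did neither (2 rose when adjusted over the list alone; median 0.19, adjusted p = 0.446), with SULTR2.1, a sulfate transporter, at 2.22 ± 0.54. Of 11 markers of meristem and flower, 1 rose, 2 fell and 8 did neither, with the same counts when adjusted over the list alone, and FUL rose by 1.75 ± 0.24. Their median was −0.04 and the test pointed downward (adjusted p = 0.957), while their mean was 0.03.

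The largest rises among genes with a symbol included LUP5, a triterpene cyclase, at 5.21 ± 0.44, RL4 and RL6, small MYB-like proteins, at 4.52 ± 0.30 and 4.28 ± 0.43, and GolS2, a galactinol synthase, at 4.1 ± 0.39. AT5G10760 had the largest rise of any gene at 5.30 ± 0.52. UMAMIT25, a membrane transporter, fell by 6.35 ± 0.93. In all, limma called 10610 of 27143 genes, of which 5672 rose and 4938 fell, and 4977 of them differed by at least 2-fold. Of the 109 genes that the naming rule took and limma called here, 99 kept their call in every alternative run for single genes. These alternatives leave out the 2-fold minimum and the fit to the 6 arrays compared. The 99 include the called genes named above that the rule took, except SULTR2.1 and PP2AA3. The call of PP2AA3 ended after scaling to the 8 reference genes. That of SULTR2.1 ended without Col-0 day 3 replicate 1 and Col-0 day 5 replicate 3 together (limma adjusted p = 0.0518). The fry test asks whether a list moves, on balance, one way, not whether it moves more than other genes. It gave adjusted p = 0.00169 for senescence-associated genes, 0.00190 for each of the autophagy, jasmonate and mitochondrial lists, 0.00784 for dark starvation, 0.0135 for cytokinin, 0.0111 for the photosystem list, 0.0397 for the Calvin cycle and 0.0178 for plastid-encoded genes. Fry also passed lists that camera did not call. These were ethylene (0.00487), senescence transcription factors (0.00963), other auxin response factors (0.0135), genes linked to ARF2 (0.0178), reference genes (0.0191), chlorophyll breakdown (0.0206) and senescence repressors (0.0487). Scaling the arrays to the reference genes, an alternative chosen after seeing the data, gave a median over all genes of −0.104, and the split became 4556 that rose and 6148 that fell; centring each array on its median gave 5066 and 5462.

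**Figure D2:**
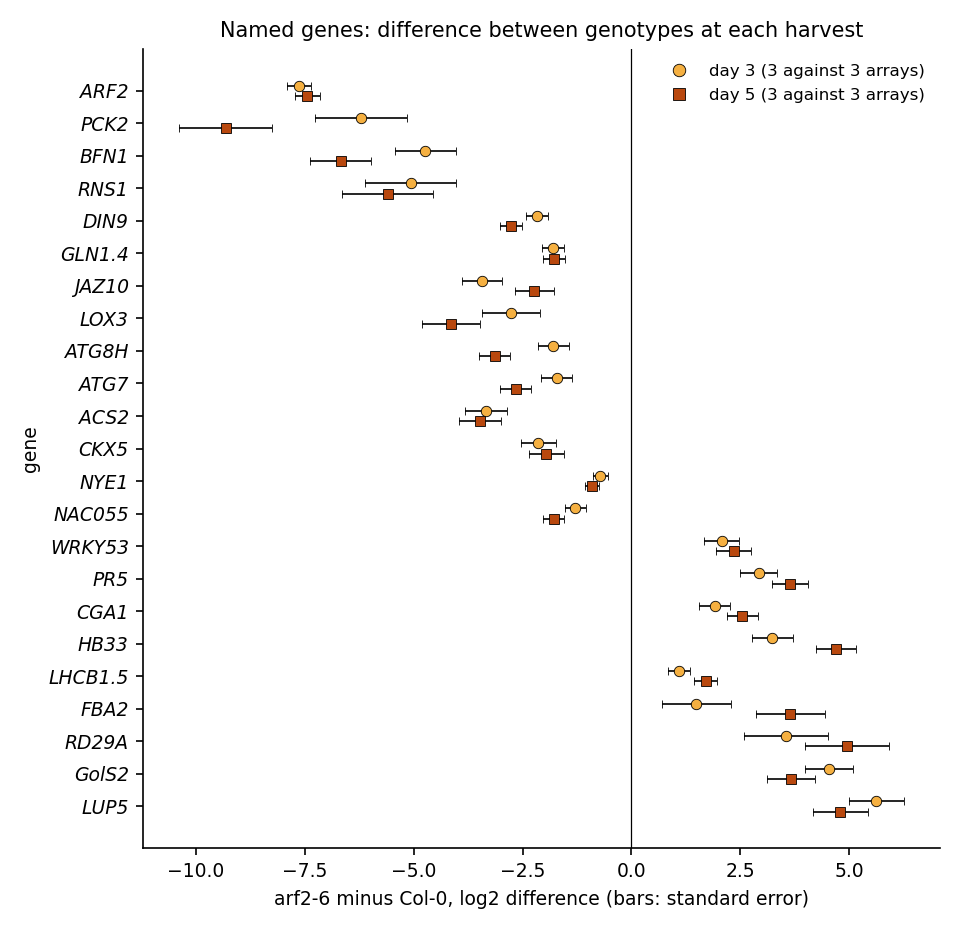
Log2 difference between arf2-6 and Col-0 of 23 named genes at day 3 and at day 5, with bars for the standard error and 3 against 3 arrays at each day. The genes shown from the lists of senescence-associated genes, autophagy and jasmonate lie below 0 at both days, with BFN1 at −4.73 and −6.68. WRKY53, a transcription factor of senescence, rose on average over both days, and LHCB1.5 lies above 0 at 1.09 and 1.70.

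At day 3 the comparison asks how the genotypes differed early in darkness. LUP5 rose by 5.62 ± 0.63, RL4 by 4.01 ± 0.43 and GolS2, which starts the synthesis of raffinose sugars, by 4.54 ± 0.55. 5PTASE11, an inositol polyphosphate phosphatase, fell by 4.82 ± 0.42, MYB97, a MYB factor best known from pollen, by 4.67 ± 0.57, JAZ10 by 3.43 ± 0.45 and DIN9 by 2.16 ± 0.26. AT1G58225 rose by 5.45 ± 0.67 and the mitochondrial ATMG01290 by 2.2 ± 0.28. ARF2 was at −7.63 ± 0.28. These 10 genes, of 54 that the naming rule took and limma called, passed in every alternative run for single genes. The fit to the 6 arrays compared, not run for single genes, called 118 genes in place of 873.

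Of 18 jasmonate genes, 5 fell, 0 rose and 13 did neither (11 fell when adjusted over the list alone), with a median of −0.71, a camera adjusted p of 2.67e-07, and adjusted p = 0.591 with an estimated correlation. Of 30 senescence-associated genes, 4 fell, 0 rose and 26 did neither (6 fell when adjusted over the list alone), with a median of −0.40, a camera adjusted p of 3.82e-05, and adjusted p = 0.591 with an estimated correlation. Of 25 autophagy genes, 4 fell, 0 rose and 21 did neither (5 fell when adjusted over the list alone), with a median of −0.28, a camera adjusted p of 0.000109, and adjusted p = 0.629 with an estimated correlation. Of 27 genes of dark starvation, 2 fell, 0 rose and 25 did neither (7 fell and 1 rose when adjusted over the list alone), with a median of −0.25, a camera adjusted p of 0.000964, and adjusted p = 0.629 with an estimated correlation. Of the 47 photosystem genes, 1 rose, 1 fell and 45 did neither (2 rose and 1 fell when adjusted over the list alone). PETE1 was at 2.1 ± 0.49 and LHCA5 at −1.20 ± 0.25, and the list had a median of 0.68, a camera adjusted p of 4.46e-08, and adjusted p = 0.629 with an estimated correlation. Of 94 mitochondrion-encoded genes, 2 rose, 0 fell and 92 did neither (1 rose when adjusted over the list alone), with a median of 0.28, a camera adjusted p of 1.30e-08, and adjusted p = 0.629 with an estimated correlation. These 6 lists passed camera without each array in turn, but without Col-0 day 3 replicate 1 the medians were −0.18 for senescence-associated genes, −0.12 for dark starvation and 0.44 for the photosystem list. By fry, senescence-associated genes (0.0188), jasmonate (0.0180) and mitochondrion-encoded genes (0.0425) passed at day 3, while autophagy (0.0756), dark starvation (0.0669) and the photosystem list (0.16) did not.

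Of 35 auxin response genes, 2 rose, 0 fell and 33 did neither (2 rose when adjusted over the list alone), with IAA29 at 5.28 ± 0.89. This list had a median of 0.41, a camera adjusted p of 0.00922, and adjusted p = 0.629 with an estimated correlation; without arf2-6 day 3 replicate 2 the camera value was 0.0561. Of 14 genes of chlorophyll breakdown, 3 fell, 0 rose and 11 did neither (6 fell and 1 rose when adjusted over the list alone), with NYE1 at −0.71 ± 0.16. Their median was −0.29, with a camera adjusted p of 0.0264, and adjusted p = 0.629 with an estimated correlation; the camera value was 0.0834 without Col-0 day 3 replicate 2 and 0.146 without arf2-6 day 3 replicate 1. Of 67 plastid-encoded genes, 0 passed limma over all genes or adjusted over the list alone, with a median of 0.10. Their camera adjusted p was 0.0284, and adjusted p = 0.823 with an estimated correlation; the camera value was 0.470 without Col-0 day 3 replicate 1, 0.176 without arf2-6 day 3 replicate 2 and 0.0723 without arf2-6 day 3 replicate 3. Of 22 ethylene genes, 3 fell, 0 rose and 19 did neither (7 fell when adjusted over the list alone), with ACS2 at −3.33 ± 0.48 and a list median of −0.11. The ethylene list had a camera adjusted p of 0.0474, and adjusted p = 0.591 with an estimated correlation. Of 21 abscisic acid genes, 2 rose, 0 fell and 19 did neither (3 rose when adjusted over the list alone), with a median of 0.78, a camera adjusted p of 0.0474, and adjusted p = 0.632 with an estimated correlation. The ethylene camera value was 0.0938 without Col-0 day 3 replicate 3, 0.0620 without Col-0 day 5 replicate 1, 0.0994 without Col-0 day 5 replicate 3, 0.0604 without arf2-6 day 3 replicate 2, 0.0723 without arf2-6 day 3 replicate 3 and 0.0509 without arf2-6 day 5 replicate 1. For abscisic acid it was 0.0799 without Col-0 day 3 replicate 2, 0.153 without Col-0 day 3 replicate 3, 0.0672 without Col-0 day 5 replicate 1, 0.0949 without Col-0 day 5 replicate 3, 0.203 without arf2-6 day 3 replicate 2, 0.0723 without arf2-6 day 3 replicate 3 and 0.0509 without arf2-6 day 5 replicate 1. The ethylene value was also 0.0584 with array weights, 0.0524 with rows averaged, 0.101 without both Col-0 day 3 replicate 1 and Col-0 day 5 replicate 3, and 0.0530 after scaling to the reference genes, the last pair chosen after seeing the data; these gave 0.516 and 0.0962 for plastid-encoded genes. For abscisic acid it was 0.0848 without dim genes. Medians also moved: without Col-0 day 3 replicate 1 they were 0.27 for auxin response, −0.21 for ethylene and 0.04 for plastid-encoded genes, without arf2-6 day 3 replicate 1 they were −0.19 for ethylene and 0.17 for plastid-encoded genes, and without Col-0 day 3 replicate 3 the latter was 0.16. Without arf2-6 day 3 replicate 2 the ethylene median was −0.20 and the abscisic acid median 0.45, and without arf2-6 day 3 replicate 3 the ethylene median was −0.07. By fry, the ethylene list passed (0.0313), while chlorophyll breakdown (0.0669), auxin response (0.134), abscisic acid (0.193) and plastid-encoded genes (0.603) did not. A pair of further lists passed with 1 array left out: the Calvin cycle without Col-0 day 5 replicate 1 (0.0465) and salicylic acid without Col-0 day 3 replicate 2 (0.0266).

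Among larger differences at day 3 that did not pass in every alternative run for single genes, PCK2 was at −6.22 ± 1.06, BFN1 at −4.73 ± 0.70, HB33 at 3.24 ± 0.47 and PR5 at 2.92 ± 0.42. Limma called 873 genes at day 3, of which 334 rose and 539 fell, and 678 of them differed by at least 2-fold. The 3 arrays of each genotype did not overlap for 9074 genes, 33.4% of those tested, where chance gives 10%. The count was 94 without Col-0 day 3 replicate 1, 544 without Col-0 day 3 replicate 2, 1419 without Col-0 day 5 replicate 1, 1489 without Col-0 day 5 replicate 3, 70 without arf2-6 day 3 replicate 2, 80 without arf2-6 day 3 replicate 3, 410 without arf2-6 day 5 replicate 1, 563 without arf2-6 day 5 replicate 2 and 436 without arf2-6 day 5 replicate 3. Of the 54 named genes that limma called, 44 lost their call without arf2-6 day 3 replicate 2. They include every called gene named at this day outside the first 10. The calls that ended were 36, 21 and 22 without Col-0 day 3 replicates 1, 2 and 3, 4 and 1 without Col-0 day 5 replicates 2 and 3, 13 and 42 without arf2-6 day 3 replicates 1 and 3, and 22, 15 and 22 without arf2-6 day 5 replicates 1, 2 and 3.

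At day 5 the same comparison asks how far the genotypes had parted. PGAZAT, a polygalacturonase of abscission zones, fell by 9.69 ± 1.92, PCK2 by 9.32 ± 1.06, UMAMIT25 by 8.23 ± 1.32 and BFN1 by 6.68 ± 0.70. LTP, a lipid transfer protein of the cell surface, rose by 6.52 ± 0.82, XTH15 by 5.8 ± 1.07 and DGR2, a cell wall protein, by 5.92 ± 0.69. ARF2 was at −7.44 ± 0.28. Among genes of photosynthesis, LHCB1.5 was at 1.70 ± 0.26, FBA2 at 3.65 ± 0.80 and HCEF1 at 3.61 ± 0.84.

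Of 47 photosystem genes, 29 rose, 1 fell and 17 did neither (34 rose and 1 fell when adjusted over the list alone), with a median of 1.1, a camera adjusted p of 2.19e-07, and adjusted p = 0.542 with an estimated correlation. Of 20 Calvin cycle genes, 11 rose, 0 fell and 9 did neither (15 rose when adjusted over the list alone), with a median of 1.07, a camera adjusted p of 9.24e-05, and adjusted p = 0.542 with an estimated correlation; without Col-0 day 5 replicate 3 the Calvin cycle median was 0.53. Of 67 plastid-encoded genes, 46 rose, 0 fell and 21 did neither (51 rose when adjusted over the list alone), with ATCG00180 at 1.22 ± 0.25 and a median of 0.61. Their camera adjusted p was 4.78e-11, and adjusted p = 0.542 with an estimated correlation. Of 94 mitochondrion-encoded genes, 41 rose, 1 fell and 52 did neither (42 rose and 1 fell when adjusted over the list alone), with ATMG00140 at 1.92 ± 0.23. Their median was 0.43, with a camera adjusted p of 2.79e-07, and adjusted p = 0.542 with an estimated correlation. Of 25 autophagy genes, 15 fell, 0 rose and 10 did neither (18 fell when adjusted over the list alone), with ATG8H at −3.14 ± 0.35 and a median of −0.66. The autophagy list had a camera adjusted p of 2.30e-07, and adjusted p = 0.542 with an estimated correlation. Of 30 senescence-associated genes, 12 fell, 0 rose and 18 did neither over all genes and when adjusted over the list alone. Their median was −0.51, with a camera adjusted p of 0.000277, and adjusted p = 0.542 with an estimated correlation.

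Of 18 jasmonate genes, 8 fell, 0 rose and 10 did neither over all genes and when adjusted over the list alone, with LOX3 at −4.14 ± 0.67. Their median was −0.52, with a camera adjusted p of 0.0124, and adjusted p = 0.542 with an estimated correlation; without Col-0 day 5 replicate 2 the camera value was 0.0670. Of 16 cytokinin genes, 5 fell, 0 rose and 11 did neither over all genes and when adjusted over the list alone, with CKX3 at −5.51 ± 1.02 and CKX2 at −7.77 ± 1.58. Their median was −0.99, with a camera adjusted p of 0.00797, and adjusted p = 0.542 with an estimated correlation; with array weights the camera value was 0.0511. Col-0 day 5 replicate 3 carried much of the cytokinin difference, and without it the median was −0.44 (adjusted p = 0.0252). Of 27 genes of dark starvation, 10 fell, 1 rose and 16 did neither over all genes and when adjusted over the list alone, with PRODH2 at −2.67 ± 0.34. Their median was −0.29, with a camera adjusted p of 0.0135, and adjusted p = 0.617 with an estimated correlation; without Col-0 day 5 replicate 2 the camera value was 0.0722. Of 15 genes of salicylic acid and defence, 2 rose, 5 fell and 8 did neither over all genes and when adjusted over the list alone, with PR5 at 3.64 ± 0.42 and CBP60G, a regulator of salicylic acid synthesis, at −3.21 ± 0.74. Their median was −2.53, with a camera adjusted p of 0.0767, which became 0.0202 without Col-0 day 3 replicate 2 and 0.00246 without Col-0 day 5 replicate 2.

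By fry, the 9 lists that camera called at day 5 passed, from 0.00603 for senescence-associated genes and autophagy to 0.0198 for the Calvin cycle. Lists that camera did not call passed fry too. These were senescence transcription factors (0.0132), flavonoid and anthocyanin (0.0143), reference genes (0.0171), other auxin response factors (0.0192), senescence repressors (0.0242), ethylene (0.0254) and genes linked to ARF2 (0.0352). Limma called 9696 genes at day 5, of which 5262 rose and 4434 fell, and 6231 of them differed by at least 2-fold. The 3 arrays of each genotype did not overlap for 13702 genes, 50.5% of those tested, where chance gives 10%. The count was 6139 without Col-0 day 5 replicate 3, 5762 without arf2-6 day 5 replicate 1 and 5438 without arf2-6 day 5 replicate 3. The genes named at this day passed in every alternative run for single genes. Scaling to the 8 reference genes, chosen after seeing the data, gave a median over all genes of −0.151, with 3977 that rose and 5711 that fell; centring each array on its median gave 4521 and 5048.

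The days had much in common. Among genes called at day 3 and at day 5, 757 had the same direction and 1 the opposite one; 293 rose, where independent lists give 64.8, and 464 fell, where they give 88.0. The overlap was 82 without Col-0 day 3 replicate 1, 496 without Col-0 day 3 replicate 2, 1270 without Col-0 day 5 replicate 1, 1155 without Col-0 day 5 replicate 3, 63 without arf2-6 day 3 replicate 2, 70 without arf2-6 day 3 replicate 3, 337 without arf2-6 day 5 replicate 1, 485 without arf2-6 day 5 replicate 2 and 356 without arf2-6 day 5 replicate 3. Across genes, which are not independent replicates, the differences at the days had a Pearson correlation of 0.782. IAA29 was among the exceptions, at 5.28 ± 0.89 at day 3 and 0.82 at day 5, where its adjusted p was 0.501.

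**Figure D3:**
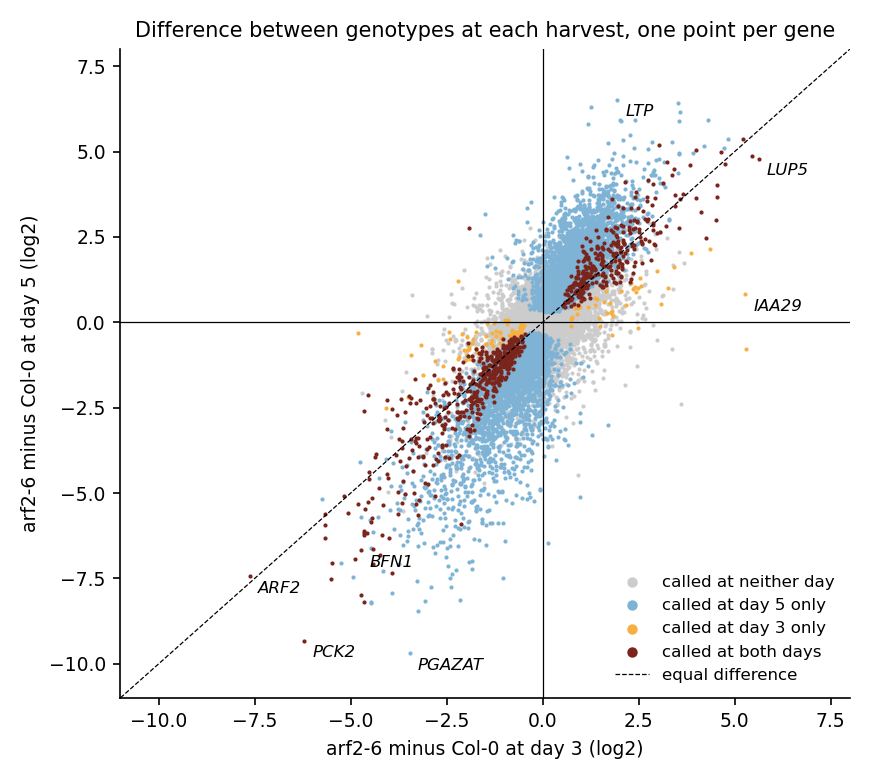
Log2 difference between arf2-6 and Col-0 of each gene at day 3 (horizontal axis) and at day 5 (vertical axis), coloured by the days at which limma called it, with a dashed line of equal differences. PCK2, at −6.22 and −9.32, and BFN1, at −4.73 and −6.68, lie below the line, and IAA29 lies near 0 at day 5.

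The comparison of days within Col-0 asks what changed in the wild type between 3 and 5 days of darkness. ERF9, an ethylene response factor that represses its targets, fell by 4.96 ± 0.49, GATA20 by 2.5 ± 0.27 and AT5G57760 by 5.8 ± 0.44, while AT1G51035 rose by 4.99 ± 0.46. These 4 genes, of 13 that the naming rule took and limma called, passed in every alternative run for single genes. The fit to the 6 Col-0 arrays alone, however, called 1 gene, a rise. LTP5, a lipid transfer protein, was at −4.32 ± 0.51, but its adjusted p was 0.0864 without Col-0 day 3 replicate 2, 0.0628 without Col-0 day 3 replicate 3 and 0.0563 without Col-0 day 5 replicate 3. MYB87, a MYB factor, was at 1.98 ± 0.22, with an adjusted p of 0.0781 without Col-0 day 3 replicate 3.

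By camera, photosynthesis lists were lower and autophagy higher at day 5. In each list below 0 members passed limma over all genes, where 5217 genes had an unadjusted p under 0.05 (no permutation was used). Single arrays of the days overlapped for some of these lists. Against the Col-0 day 3 means, the photosystem median was −0.36 on Col-0 day 3 replicate 1 and −0.13 on Col-0 day 5 replicate 1. For the Calvin cycle these were −0.28 and −0.12, and for autophagy 0.21 and 0.10. The plastid-encoded medians did not overlap. Of 67 plastid-encoded genes 36 fell when adjusted over the list alone, with a median of −0.46, a camera adjusted p of 9.07e-18, and adjusted p = 0.662 with an estimated correlation. Of 47 photosystem genes 11 fell when adjusted over the list alone, with a median of −0.68, a camera adjusted p of 2.60e-10, and adjusted p = 0.662 with an estimated correlation. LHCB5, an antenna protein, was at −2.51 with an adjusted p of 0.0679. Of 20 Calvin cycle genes 1 fell when adjusted over the list alone, with a median of −1.05, a camera adjusted p of 8.94e-07, and adjusted p = 0.662 with an estimated correlation. The 25 autophagy genes had a median of 0.26, with 0 past limma when adjusted over the list alone, a camera adjusted p of 0.00102, and adjusted p = 0.662 with an estimated correlation. Without Col-0 day 5 replicate 3 the medians were −0.28 for plastid-encoded genes, −0.43 for the photosystem list and −0.63 for the Calvin cycle. The arrays that stood apart moved with these lists: against replicates 2 and 3, Col-0 day 3 replicate 1 had medians of −0.54 for the photosystem list, −0.41 for the Calvin cycle, −0.22 for plastid-encoded genes and 0.31 for autophagy. Against replicates 1 and 2, Col-0 day 5 replicate 3 had medians of −0.65, −1.17, −0.53 and 0.32 for the same lists. Epidermis and guard cell markers were at −0.63 on the former array and −0.53 on the latter.

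The 16 cytokinin genes had a median of 0.41, with 0 past limma when adjusted over the list alone, a camera adjusted p of 0.0417, and adjusted p = 0.662 with an estimated correlation. The cytokinin camera value was 0.0672 without Col-0 day 3 replicate 2, 0.0937 without Col-0 day 3 replicate 3, 0.0612 without Col-0 day 5 replicate 1, 0.189 without Col-0 day 5 replicate 3, and 0.0511, 0.0533 and 0.0528 without arf2-6 day 5 replicates 1, 2 and 3. The cytokinin value was also 0.0517 after median centring, 0.0687 without dim genes, 0.0703 with array weights and 0.0678 after scaling to the reference genes, chosen after seeing the data. On Col-0 day 5 replicate 3 the cytokinin median lay 1.15 above that of replicates 1 and 2, and the change in the list was 0.68, 0.93 and 0.24 without Col-0 day 5 replicates 1, 2 and 3. The 18 glucosinolate genes had a median of −0.62, with 0 past limma when adjusted over the list alone, a camera adjusted p of 0.0231, and adjusted p = 0.662 with an estimated correlation. The glucosinolate camera value was 0.0937 without Col-0 day 3 replicate 3, 0.384 without Col-0 day 5 replicate 2, where the median was −0.20, and 0.0687 without dim genes. By fry, the flavonoid and anthocyanin list passed between the days in Col-0 (median −0.13, adjusted p = 0.0133), while the lists called by camera did not: plastid-encoded genes (0.0754), the photosystem list and the Calvin cycle (0.147 each), autophagy and cytokinin (0.223 each) and glucosinolate (0.255). The MYB factor gene PAP2 was at −1.4 with an adjusted p of 0.0668. Some lists that did not pass camera passed it in alternatives: the jasmonate (0.0193) and dark starvation (0.0355) lists without Col-0 day 5 replicate 3 and with array weights (0.0176 and 0.0119), salicylic acid without Col-0 day 5 replicate 2 (0.0267), and abscisic acid without arf2-6 day 3 replicate 1 (0.0297). The phloem and xylem list passed with array weights (0.0397) and without Col-0 day 5 replicate 3 (0.0192), arf2-6 day 3 replicate 1 (0.0420) or arf2-6 day 3 replicate 2 (0.0443).

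Limma called 34 genes between the days in Col-0, of which 11 rose and 23 fell, and each differed by at least 2-fold. The 3 arrays of each day did not overlap for 4155 genes, 15.3% of those tested, where chance gives 10%. The count was 958 without Col-0 day 3 replicate 1, 13 without Col-0 day 3 replicate 2, 11 without Col-0 day 3 replicate 3, 1789 without Col-0 day 5 replicate 1, 70 without Col-0 day 5 replicate 2, 16 without arf2-6 day 3 replicate 3, and 17, 19 and 16 without arf2-6 day 5 replicates 1, 2 and 3. Without both Col-0 day 3 replicate 1 and Col-0 day 5 replicate 3, an alternative chosen after seeing the data, it was 670.

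In arf2-6 the comparison of days asks what changed in the mutant over the same time. The genes with the smallest unadjusted p did not pass limma and are given as values. AOX1C, an alternative oxidase of mitochondria, was at 1.89 ± 0.23, the chaperone HSP70 at 1.61 ± 0.22, Cpn60beta2, a plastid chaperonin, at 1.29 ± 0.18, AT2G29500 at 1.91 ± 0.27 and XND1, a xylem NAC factor, at −1.13 ± 0.17, each with an adjusted p of 0.227.

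Of 35 auxin response genes 1 fell when adjusted over the list alone, with a median of −0.63, a camera adjusted p of 9.55e-09, and adjusted p = 0.384 with an estimated correlation. IAA29 was at −5.22 with an adjusted p of 0.383. Of 18 jasmonate genes 3 rose when adjusted over the list alone, with a median of 0.33, a camera adjusted p of 3.89e-05, and adjusted p = 0.657 with an estimated correlation. The 94 mitochondrion-encoded genes had a median of 0.18, a camera adjusted p of 2.42e-07, and adjusted p = 0.763 with an estimated correlation. The 47 photosystem genes had a median of −0.28, a camera adjusted p of 4.28e-08, and adjusted p = 0.941 with an estimated correlation. The 15 genes of salicylic acid and defence had a median of −0.60, a camera adjusted p of 0.00417, and adjusted p = 0.956 with an estimated correlation; the camera value was 0.230 without arf2-6 day 3 replicate 1, with a median of −0.20. Without arf2-6 day 5 replicate 1 the jasmonate median was 0.49, and without arf2-6 day 5 replicates 2 and 3 the medians were −0.13 and −0.43 for the photosystem list and 0.32 and 0.12 for mitochondrion-encoded genes. By fry, these lists did not pass, at 0.456 for auxin response, 0.560 for jasmonate and mitochondrion-encoded genes, and 0.897 for the photosystem and salicylic acid lists. In the last 3 of these lists 0 genes passed limma when adjusted over the list alone. Without arf2-6 day 3 replicate 1 the lists of dark starvation (0.0137), cell expansion (0.0384), and phloem and xylem (0.0384) passed camera, and so did abscisic acid genes, with a median of −0.30 (0.0153), against 0.05 with all arrays. The phloem and xylem list also passed without arf2-6 day 5 replicate 3 (0.0107), and autophagy without arf2-6 day 5 replicate 2 (0.0211). Limma called 0 genes between the days in arf2-6, and 7 without arf2-6 day 3 replicate 1. Of 27143 genes, 1259 had an unadjusted p under 0.05 (no permutation was used), a smaller share than 0.05. The fit pools the spread of a gene over the 4 groups. The median SD was 0.28 and 0.35 in Col-0 at days 3 and 5, against 0.20 in each arf2-6 group. Array weights, which set noisier arrays lower, raised the count, as given in the part on processing. The 0 calls therefore do not show that the mutant stayed unchanged. The 3 arrays of each day did not overlap for 4553 genes, 16.8% of those tested, where chance gives 10%.

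The interaction asks whether the change from day 3 to day 5 differed between the genotypes. One gene passed limma, AT2G04046. Its mean log2 level was 3.84 in Col-0 at day 3 and 7.93 at day 5, and 3.31 and 3.56 in arf2-6, an interaction of −3.83 ± 0.39 with an adjusted p of 0.0495. All of these means but that of Col-0 at day 5 lie below the lower quartile of the intensities, so the size of this interaction is uncertain. The adjusted p of AT2G04046 was 0.0921 without Col-0 day 3 replicate 2, 0.0913 without Col-0 day 3 replicate 3, 0.115 without Col-0 day 5 replicate 2 and 0.0783 without Col-0 day 5 replicate 3. It was 0.0584, 0.266 and 0.150 without arf2-6 day 3 replicates 1, 2 and 3, and 0.282, 0.292 and 0.284 without arf2-6 day 5 replicates 1, 2 and 3. By camera, the time change in arf2-6 minus that in Col-0 was above 0 for plastid-encoded genes (median 0.47, adjusted p = 8.17e-14) and Calvin cycle genes (0.95, adjusted p = 0.000115) and below 0 for autophagy genes (−0.35, adjusted p = 0.000102); each had adjusted p = 0.697 with an estimated correlation. Autophagy genes had a median of 0.26 over time in Col-0 and −0.10 in arf2-6, and Calvin cycle genes had medians of −1.05 and −0.05. Without Col-0 day 5 replicate 3 the interaction medians were 0.29 for plastid-encoded genes and 0.51 for the Calvin cycle.

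Photosystem genes had an interaction median of 0.41 (camera adjusted p = 0.0181, and adjusted p = 0.697 with an estimated correlation). The photosystem camera value was 0.0842, 0.0800, 0.103 and 0.248 without Col-0 day 3 replicate 2, Col-0 day 3 replicate 3, Col-0 day 5 replicate 2 and Col-0 day 5 replicate 3, and 0.170, 0.0699 and 0.167 without arf2-6 day 3 replicate 1, arf2-6 day 5 replicate 1 and arf2-6 day 5 replicate 3. Cytokinin genes had a median of −0.43 (camera adjusted p = 0.0330, and adjusted p = 0.697 with an estimated correlation). The cytokinin camera value was 0.0653, 0.0712, 0.0528 and 0.138 without Col-0 day 3 replicate 2, Col-0 day 3 replicate 3, Col-0 day 5 replicate 1 and Col-0 day 5 replicate 3, and 0.0636 and 0.0699 without arf2-6 day 3 replicate 2 and arf2-6 day 5 replicate 1. Genes of salicylic acid and defence had a median of −0.93 (camera adjusted p = 0.0486, and adjusted p = 0.697 with an estimated correlation). The salicylic acid camera value was 0.509, 0.313 and 0.221 without Col-0 day 3 replicate 2, Col-0 day 5 replicate 1 and Col-0 day 5 replicate 3, and 0.186, 0.0931 and 0.0734 without arf2-6 day 3 replicate 1, arf2-6 day 5 replicate 1 and arf2-6 day 5 replicate 2. Other alternatives also ended these calls: for salicylic acid median centring (0.0936), array weights (0.342), averaged rows (0.0547), and, chosen after seeing the data, leaving out both Col-0 day 3 replicate 1 and Col-0 day 5 replicate 3 (0.0852) and scaling to the reference genes (0.131), for cytokinin array weights (0.114) and that scaling (0.0522), and for the photosystem list leaving out dim genes (0.0568). Interaction medians that moved were 0.67 and 0.19 for the photosystem list without Col-0 day 5 replicates 1 and 3, and −0.94, −0.10 and −0.27 for cytokinin without Col-0 day 5 replicate 2, Col-0 day 5 replicate 3 and arf2-6 day 3 replicate 1. For salicylic acid they were −1.42 and −0.31 without Col-0 day 3 replicates 1 and 2, −0.60, −2.36 and −0.34 without Col-0 day 5 replicates 1, 2 and 3, and −0.50 without arf2-6 day 3 replicate 1. In these lists 0 members passed limma over all genes or adjusted over the list alone, where 2261 genes had an unadjusted p under 0.05 (no permutation was used). Lists that passed camera without 1 array were auxin response without Col-0 day 5 replicate 2 (0.0307) or arf2-6 day 3 replicate 1 (0.000147), abscisic acid without arf2-6 day 3 replicate 1 (0.000369), and mitochondrion-encoded genes without arf2-6 day 3 replicate 1 (0.0161) or arf2-6 day 5 replicate 2 (0.000306). The glucosinolate list did so without Col-0 day 5 replicate 1 (0.0438), Col-0 day 5 replicate 3 (0.0346) or arf2-6 day 3 replicate 3 (0.0222). By fry, the lists called here did not pass, at 0.524 for plastid-encoded genes, the Calvin cycle, autophagy and cytokinin, and 0.598 for the photosystem and salicylic acid lists. The gene count was 35 without Col-0 day 3 replicate 1, 99 without Col-0 day 5 replicate 1, 3 without arf2-6 day 3 replicate 1, and 0 without Col-0 day 3 replicate 2, Col-0 day 5 replicate 3, or any other arf2-6 array.

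**Figure D4:**
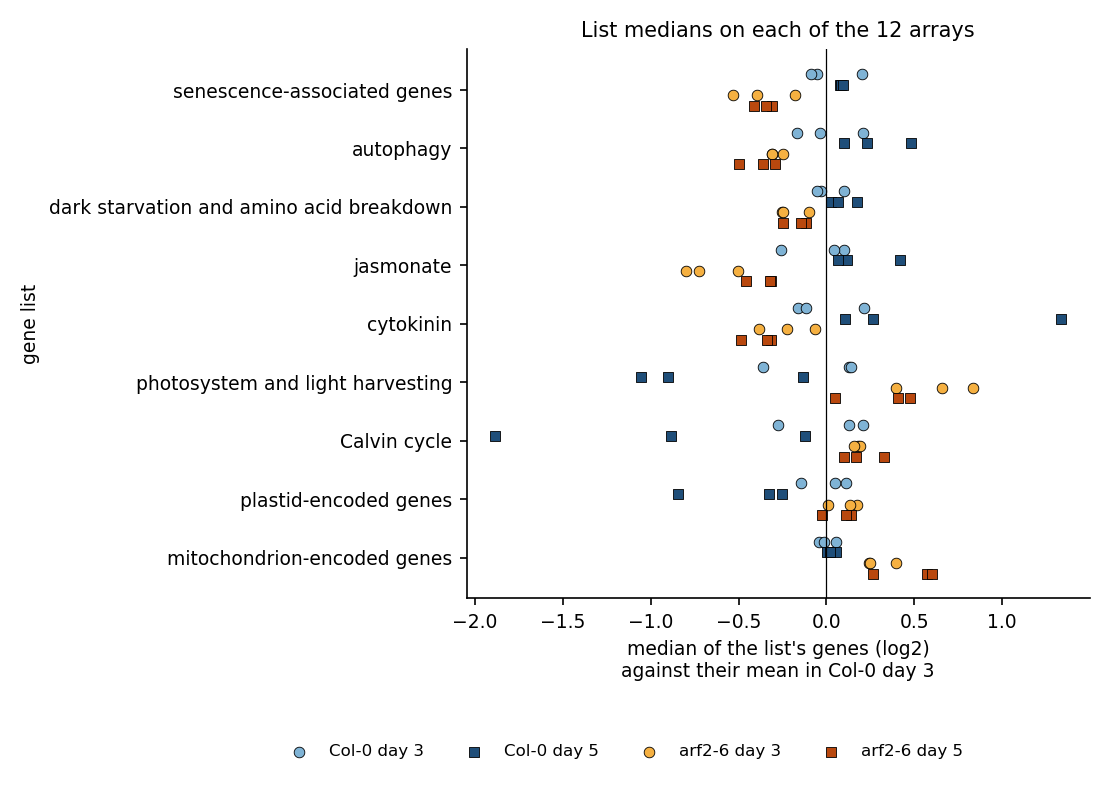
Median of 9 gene lists on each of the 12 arrays, as the log2 difference from the mean of the same genes in Col-0 at day 3. Senescence-associated genes were lower on all 6 arf2-6 arrays than on all 6 Col-0 arrays, and Calvin cycle medians of Col-0 at day 5 ranged from −1.89 to −0.12.

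Set against the change over time in the wild type, the genotype difference ran the other way across genes. The difference at day 5 had a Pearson correlation of −0.810 (Spearman −0.777) with the change from day 3 to day 5 in Col-0, and the difference at day 3 one of −0.405 (Spearman −0.394). Each pair shares 3 Col-0 arrays. Simulated groups with no effect gave mean correlations of −0.485 (central range −0.851 to 0.133) and 0.485 (central range −0.188 to 0.868). The observed values lay inside the former central range and outside the latter. A central range leaves out the outermost draws at both ends, so some sets with no effect lie outside it too. The covariances were −0.815 and −0.250, where shared arrays alone give −0.101 and 0.101, a difference of −0.714 and −0.351. The expected values and the simulated ranges use the spread pooled over the 4 groups. The shared Col-0 arrays had a larger spread, with a median SD of 0.28 at day 3 and 0.35 at day 5, against 0.20 in each arf2-6 group. At day 5 the shared arrays may therefore give a larger part of the covariance, and the size of the excess is uncertain. Without Col-0 day 3 replicate 1 the day 5 correlation was −0.854, outside the central range simulated for those arrays. Without Col-0 day 5 replicate 2 the day 3 correlation was −0.338, inside its central range. Part of any excess may come from the shared Col-0 arrays, which 3 per group do not allow to be divided, where leaving out arrays moved the day 3 correlation between −0.456 and −0.229. The changes over time in Col-0 and arf2-6, which share no arrays, had a correlation of 0.119 (Spearman 0.0606), inside the simulated central range of −0.669 to 0.684.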

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

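Tests of a label exchange, of leaf stage, of shared organelle yield, and of splits for the interaction were chosen only after the results below were seen.

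Far fewer genes were called between genotypes at day 3 (873) than at day 5 (9696). A candidate explanation is that Col-0 day 3 replicate 1 widened the spread: without it the count was 94, but leaving out an array also costs precision (70 and 80 without arf2-6 day 3 replicates 2 and 3), and array weights, which keep every array, gave 5946 against 12264 at day 5, so this stays open. Another is that the genotypes differed more at day 5. Over the 10610 genes called for the average, day 5 differences were 1.45 times those at day 3 by a regression slope. The slope was 1.57 without Col-0 day 3 replicate 1, and ran from 1.29 to 1.63 with 1 array left out. A larger difference at day 5 would give such slopes. These genes were chosen from the same differences, however, so the slope cannot settle how much larger the day 5 differences were. Of the splits of the 6 arrays at day 3, 1 of 10 called as many genes as the labels, and the highest other count was 0; at day 5 it was 1 of 10, with a highest other count of 1. These 10 splits are too few for a share under 0.05, and how far precision and size each set the counts stays open.

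The Col-0 arrays were spread along one axis, with day 3 replicate 1 among the day 5 arrays. Exchanging the labels of that array and Col-0 day 5 replicate 1 raised the genes called between days in Col-0 from 34 to 3033. Exchanges with replicates 2 and 3 gave 6 and 0. A swap could explain the rise, but that exchange also sorts the Col-0 arrays by their place on the first component. Such sorting can raise the count whatever caused the axis, so the count cannot tell a swap from another cause. Markers of epidermis and guard cells were at −0.629 on that array, and the other marker lists and the photosystem list were lower too, so added cells of those types are not seen, but a changed mix of cell types stays open. Leaves at different stages of senescence may also fit, since the deviations of both outer Col-0 arrays correlated at 0.505 across genes. Both arrays were picked as the lowest of their groups on the first component. The correlation therefore cannot tell leaf stage from any other cause of that axis. For the days in Col-0, 2 of 10 splits, too few for a share under 0.05, called as many genes as the labels (34), and the highest other count of 3033 points to structure of the samples. Which of these explanations holds stays open; an exchange within Col-0 leaves the mean of the average comparison unchanged.

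Plastid-encoded and mitochondrion-encoded transcripts were both higher in arf2-6. One shared yield or labelling of organelle RNA per array could raise both. Their medians moved apart by 0.487 between days in Col-0 (0.312 without Col-0 day 5 replicate 3, 0.595 without Col-0 day 5 replicate 1). That gap holds only Col-0 arrays, so it cannot decide the difference between genotypes. Over the 12 arrays, deviations of both medians from their group means correlated at −0.0999 (p = 0.845 by 10000 permutations within groups). This shows no shared yield among arrays of a group, but a yield common to the arf2-6 arrays stays open for these transcripts. RMA scaling that lifted genes of a like level could raise them too, but nuclear genes matched on mean level had a median of 0.0528, against 0.373 for organelle genes, which argues against it. What raised these transcripts stays open.

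For the average over both days, 1 of 100 splits drawn within each day, the labels as given, called as many as 10610 genes, so chance can be excluded there; the highest other count was 7169, for an exchange of Col-0 day 3 replicate 2 and arf2-6 day 3 replicate 1. For the interaction the average genotype effect was first taken out of each gene, and 6 of 100 drawn splits called at least the 1 gene of the labels as given, so chance cannot be excluded. The highest other count for the interaction was 202, which points to structure of the samples. Between days in arf2-6, 10 of 10 splits, too few for a share under 0.05, called as many genes as the labels. Limma called 0 genes there and in the highest other split. With the labels as given, 1259 of 27143 genes had an unadjusted p under 0.05 (no permutation), a smaller share than 0.05.

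The gene AT2G04046 had an interaction of −3.83. The photosystem list had an interaction median of 0.408. The Calvin cycle list had one of 0.951. The list of salicylic acid and defence had one of −0.926. The cytokinin list had one of −0.433. The autophagy list had one of −0.346. Plastid-encoded genes had one of 0.469. Of rows of further transcript models, 6 passed in the direction opposite to the row kept.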

How the results depend on the processing

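With array weights the counts rose to 5946 at day 3, 3453 between days in Col-0, 591 in arf2-6 and 340 for the interaction; array weights set the noisier arrays lower, and the cause was not tested further. With a trended and robust model the Col-0 days gave 53. Fits to the 6 arrays compared gave 118 at day 3, 5674 at day 5 and 1 between days in Col-0. A 2-fold minimum gave 6231 at day 5 and 4977 for the average. The interaction gave 0 after median centring, without dim genes and after scaling to the 8 reference genes, an alternative chosen after seeing the data. Without dim genes the overlap of days was 1145. Without both outer Col-0 arrays, also chosen after seeing the data, day 3 gave 273, the Col-0 days 670 and the interaction 39.

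With replicate number as a block the counts were 174 at day 3, 18 between days in Col-0 and 0 for the interaction, and 7850 at day 5. With the block the salicylic acid list passed camera at day 5 (0.0159) and for the average (0.0428), and the phloem and xylem list between days in Col-0 (0.0462), while the abscisic acid list at day 3 did not (0.0517). Deviations of equally numbered arrays correlated at −0.490, 0.208 and −0.256 between days in Col-0, at 0.347, 0.283 and 0.0446 between genotypes at day 3 and at 0.0249, 0.0620 and −0.0683 at day 5, so not every array went best with its own number, and the replicate numbers were not taken as pairs.

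With 1 array left out the counts ran from 70 to 1489 at day 3, 5438 to 11201 at day 5, 8102 to 11828 for the average, 11 to 1789 between days in Col-0, 0 to 7 in arf2-6, 0 to 99 for the interaction and 63 to 1270 for the overlap. The correlations with the Col-0 time change ran from −0.456 to −0.229 for day 3 and −0.868 to −0.715 for day 5, the former at −0.338 without Col-0 day 5 replicate 2 and the latter at −0.854 without Col-0 day 3 replicate 1; that of the time changes ran from 0.0283 to 0.221. The direction of the abscisic acid list between days in arf2-6 turned to −0.304 without arf2-6 day 3 replicate 1, the lowest value with 1 array left out; the highest was 0.445. Sign changes of results not called are not counted as turned.

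Under scaling to the reference genes the average gave 10704 calls, with 4556 that rose and 6148 that fell in place of 5672 and 4938, and day 5 gave 9688, with 3977 and 5711 in place of 5262 and 4434. Median centring turned the majority too, to 5066 and 5462 for the average and 4521 and 5048 at day 5. That scaling brought the median of all genes to 0.145 between days in Col-0. Of the named genes, 10 of 54 calls held at day 3 under the alternatives run for single genes (not the 2-fold minimum or the fits to 6 arrays), 88 of 112 at day 5, 99 of 109 for the average, 4 of 13 in Col-0 and 0 of 1 for the interaction. Of list calls by camera, 6 of 11, 6 of 9, 8 of 9, 4 of 6, 4 of 5 in arf2-6 and 3 of 6 held in the alternatives other than fry and the estimated correlation; 0 passed with the latter, and with fry 24 were lost, those of the Col-0 days, the arf2-6 days and the interaction and most of day 3.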

Other observations

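Random sets, neighbour shuffles and the tests of further transcript models were chosen only after the family and neighbour results were seen.

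Gene families defined by symbol were also compared for the average over both days. A family was the genes whose symbols share the letters before the first digit, so members need not share a function. By camera 22 of 177 passed, against at most 1 in random sets, and 0 passed with an estimated correlation, where the families below had adjusted p values of 0.697 to 0.725. Among families that passed camera with higher levels in arf2-6, EMB had the smallest camera adjusted p (4.92e-05), and of its 160 genes 73 rose and 12 fell (median 0.47). Of 12 genes with a TOC symbol, used for proteins of chloroplast import but also for the clock gene TOC1, 9 rose and 1 fell (median 0.76). Of 14 TIM genes of mitochondrial import 7 rose (0.51), and of 13 MEF genes, which edit mitochondrial transcripts, 7 rose (0.95). Of 14 PTAC genes of the plastid chromosome 6 rose (0.56), and of 17 TCP factors of leaf growth 9 rose (0.69). The import families TIC and TOM did not pass camera (adjusted p = 0.482 and 0.591). Among families that passed with lower levels, of 29 VPS genes of vacuolar sorting 14 fell and 2 rose (−0.32), of 18 PRA genes 11 fell (−0.50), and of 15 SEC genes 8 fell (−0.35), while the traffic families SYP, VAMP, EXO, RABA and AGD did not pass (adjusted p = 0.884, 0.403, 0.27, 0.101 and 0.0947). Of 79 NAC factors 26 fell and 5 rose (−0.22), of 12 SDH genes 6 fell (−0.37), and of 10 JAZ repressors 8 fell (−1.19). Not every family that passed is named, and no rule set the choice. By fry, 87 of 177 families passed, where 100 draws of random sets of the same sizes gave a median of 63 and at most 80. A candidate explanation is that families shift no more than random sets. More families passed than random sets did, but random sets do not keep the correlation between members of a family. The excess therefore cannot tell a shift of families from members that vary together, and this stays open.

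Large differences sat side by side on chromosomes more often than in shuffled orders. Among 256 genes with a difference of at least 3 that passed and whose arrays did not overlap between genotypes, 10 adjacent pairs went one way, where 1000 shuffles gave a mean of 1.43 and at most 6. They include HB33 at 3.97 beside RL6 at 4.28, and CYP76C2 at −4.15 beside CYP76C3 at −3.58, cytochromes P450, the last pair chosen for naming after their values were seen. Over all 26550 adjacent pairs, 10.1% passed in one direction, where shuffles gave at most 8.19%. Among the 20 genes nearest to ARF2, 10 passed, where 10610 of 27143 did over all genes, and the share was 11.1% of 18 pairs. This argues against the candidate explanation that linkage or the insertion at ARF2 changed most of these neighbours in one direction. So few pairs cannot exclude a short run, and they do not cover a wider segment.

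Of 4381 rows of further transcript models, 1891 passed, 1550 of them in the direction of the row kept and 6 opposite. Among those opposite, AT3G42180 was at 0.58 in the row kept and −2.18 in the other, and AT1G12672 at 1.08 and −1.01; both were chosen for naming after their values were seen.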
